A study of Drosophila melanogaster with 12 samples.

How the data were processed

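The study sequenced mNET-seq libraries of S2 cells, 2 replicates in each of 6 groups, and each library was placed in its group by its title. The durations of RNAi are read from the series' design text and are not stated per library. Per the submitters' processing notes, reads were handled with cutadapt 2.8, STAR 2.7.4a, SAMtools 1.20 and the dm6 build, and DESeq2 is also named there without a role. None of those steps could be checked here, because the only file analysed was a series-wide annotation of transcription units. Coverage and counts of the libraries were not used here, so no test between RNAi groups, no replicate error and no depth is given, and the planned tests of changed genes were not run.

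Per the file header, the annotation was written with rtracklayer 1.48.0, and its source field names a merge of database versions. How the authors merged genes is not given in the sources used here. Each line gives a chromosome, a start and an end (both 1-based), a strand, a length in bp, gene symbols, FlyBase gene IDs and transcript IDs, and the score field is empty in every line. The file was compared with the RefSeq gene table of Release 6, the same assembly. Gene symbols were matched by current symbol (14059 genes), then by locus tag or a synonym held by a single free gene of the same chromosome (3534 genes), which left 105 of 17698 genes unmatched. Matching by FlyBase gene ID, the planned way, was not possible because the table carries no such IDs. Of units with all genes matched, 99.2% had exactly the start and end of the union of their genes' spans. With spans this alike, the gene table is not an independent check of the units. In 1095 multi-gene units the spans formed 1 overlapping chain, and in 1 unit they did not.

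The main set was X against arms 2L, 2R, 3L and 3R. A gap is the number of bases to the nearest other unit, and 0 where units overlap or touch. An overlap is at least 1 bp. A divergent pair has starts on opposite strands, facing away from each other and at most 1000 bp apart. Lengths and gaps (plus 1 bp) were compared on the log2 scale as X minus autosome medians, with a two-sided permutation test of 100000 resamples and 95% intervals from 2000 bootstrap draws over units. Shares were compared with two-sided Fisher's exact tests, with normal 95% intervals for differences and exact binomial intervals for single shares. For the share of genes with a unit, whole blocks of 100 kb and of 1000 kb with all their protein-coding genes were also moved between X and autosomes in a two-sided permutation test of 100000 resamples, added after seeing the data. The 5 comparisons were adjusted together with the Benjamini-Hochberg method and a threshold of 0.05. For an alternative, its p took the place of the main p among the 5, with no adjustment for the number of alternatives tried. These tests treat units as exchangeable, and neighbouring units are not independent, so each comparison was also made with the arm as the unit. The units are an annotation and not a sample, so the intervals describe only variation among units.

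The permutation test was tested on simulated data made from the real unit lengths. With a shift of 0.3 on the log2 scale added to X, all 50 simulations of the length comparison over 15739 units passed 0.05, and the mean estimate was 0.31. With no shift, 4% passed. The lengths were shuffled over units in every simulation, so a rate near 0.05 without a shift was fixed in advance. The simulations therefore check the code and do not test the effect of dependence between neighbouring units. The gap, overlap and divergent distances of 120 simulated intervals were checked against a plain pairwise loop, with 0 mismatches. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

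Before the data were examined, the 5 comparisons, most of their alternatives and the named genes were fixed. The named genes are every member of 8 lists (MSL complex, NSL complex, MSL recruitment and partners, pausing and early elongation, Pol II subunits, heat shock genes, X-linked genes of general use, and Pof) and the 3 longest units of X and of the autosomal arms. Other genes are named only as neighbours of these or, for the run of unmatched X genes and the units with the most genes, after their values were seen. Alternatives covered the minimum length, the summary, the autosomes compared, the overlap, the strand of neighbours, the divergent distance and the gene classes of the match. Added after seeing the data were units that hold 1 gene or only protein-coding genes, matching by symbol only or also by exact span, listed units that hold only protein-coding genes in the test of divergent pairs, and 2 treatments of runs of unmatched genes, which were left out or counted once.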

Results

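The series profiled RNA polymerase II in Drosophila S2 cells, a cultured male fly line. The assay was mNET-seq, which sequences the nascent RNA held by immunoprecipitated polymerase. Its 12 libraries fell into 6 groups of 2 replicates each. Either total Pol II or Pol II phosphorylated at serine 5 of its C-terminal domain was profiled after control RNAi, MSL1 RNAi or MOF RNAi. MSL1 is a scaffold protein of the male-specific lethal (MSL) complex, and MOF is the histone H4 lysine 16 acetyltransferase of that complex. The MSL complex raises transcription of the male X chromosome, so the design asks how polymerase on X genes responds when the complex is depleted. As the design text reads, RNAi lasted 2 days for MSL1 and the control and 4 days for MOF, though durations are not stated library by library. On that reading the MOF comparison changes target and duration together. The deposited file analysed here was the annotation of transcription units made for the study, and it carried a value for 0 of the 12 libraries. Coverage of the libraries was not analysed here, so no effect of either RNAi on any gene, msl-1 and mof included, is reported, and the sequencing depth is unknown. What follows describes the units, on the dm6 build, with X set against the 4 large autosomal arms.

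The annotation placed 15960 transcription units on the 7 chromosomes and arms 2L, 2R, 3L, 3R, X, 4 and Y, and 15991 units with the mitochondrial genome included. These named 17698 genes, each in 1 unit, and were split almost evenly by strand, with 7996 on plus and 7995 on minus. X held 2399 units with 2671 genes. That was 15.2% of the 15739 units on X and the 4 large autosomal arms (95% exact binomial interval 14.7 to 15.8%), beside 15.4% of the genes of the RefSeq gene table on the same arms. Chromosome 4 held 109 units and Y held 112. No unit overlapped another on its own strand, and 1144 units (7.15%) held more than 1 gene. The multi-gene share was 7.34% on X and between 7.06% and 7.34% on the 4 autosomal arms.

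All 7 genes of the MSL complex list had a unit, 3 of them on X. The unit of msl-1 (FBgn0005617), the gene of the MSL1 RNAi target, spanned 5081 bp on the minus strand of 2L from 18683720 to 18688800. It held no other gene and overlapped no unit, but its nearest neighbour lay only 4 bp away. The start of the msl-1 unit lay 728 bp from that of CG10336 on the other strand. The unit of mof (FBgn0014340), the other RNAi target, spanned 3014 bp on the minus strand of X from 5873840 to 5876853. It also held 1 gene, was free of overlap, and lay 146 bp from its nearest neighbour. The unit of msl-2, whose protein restricts the complex to males, ran from 3462218 to 3466112 on the minus strand of 2L. It included mir-4971, and its start lay 45 bp from the start of ND-PDSW, a mitochondrial complex I subunit gene. The unit of mle, the RNA helicase of the complex, spanned 5922 bp on 2R from 5974857 to 5980778 and stood alone. Of the 2 non-coding RNAs of the complex, roX2 had a unit of 1368 bp on the plus strand of X from 11579065 to 11580432 with no overlap. The roX1 unit, 5468 bp on the minus strand of X from 3857230 to 3862697, overlapped the unit of ec on the other strand by 392 bp. The msl-3 unit, on 3L from 7123213 to 7125533, overlapped that of form3 by 85 bp.

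**Figure D1:**
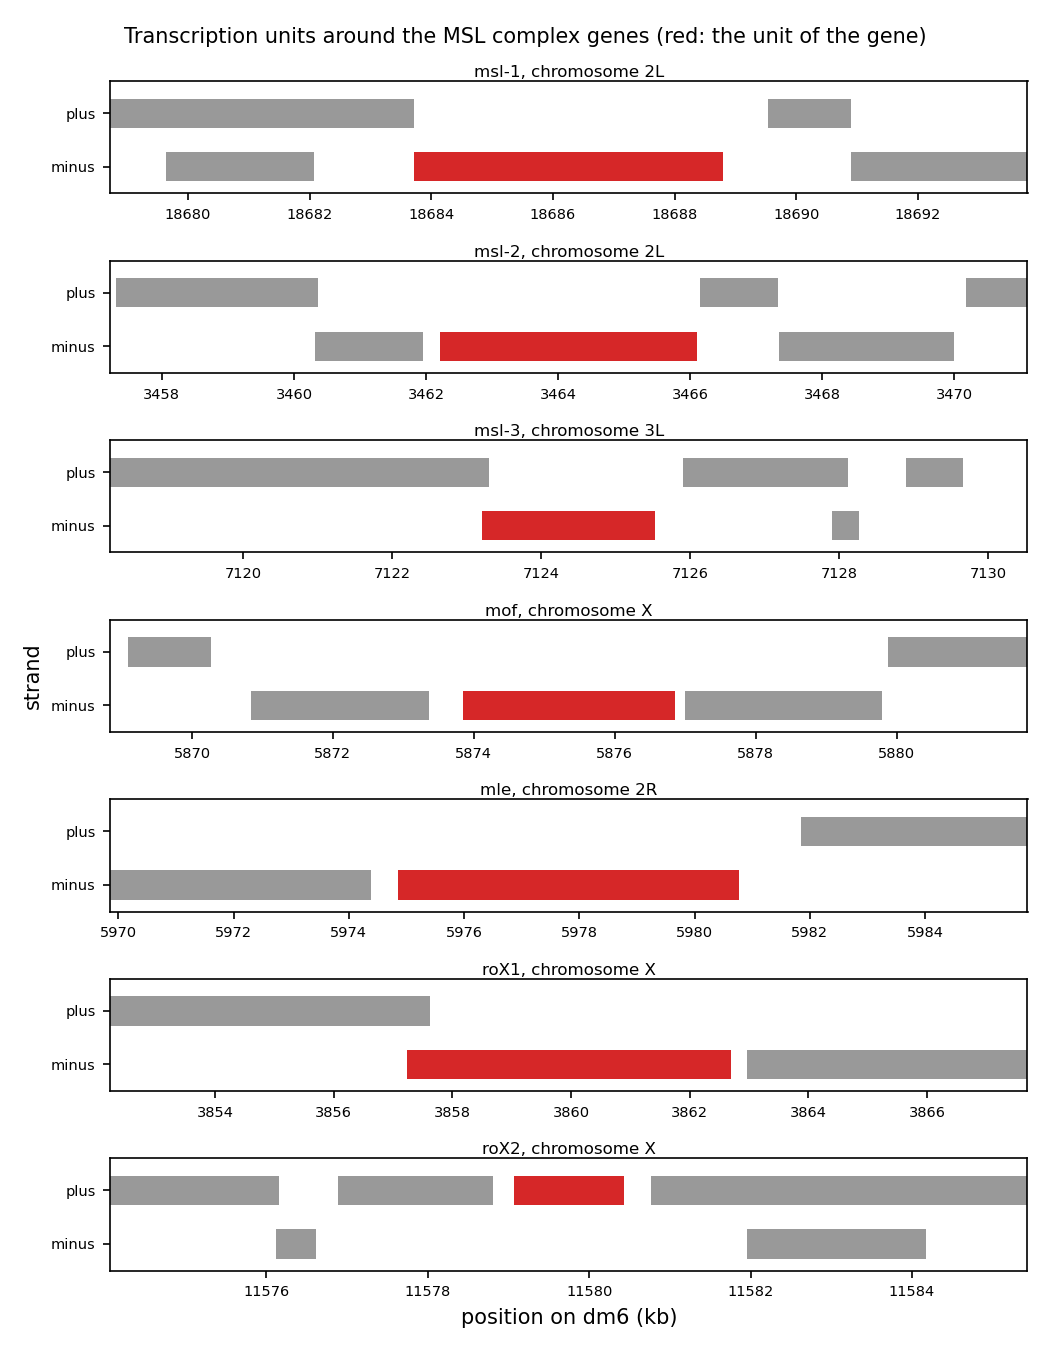
Transcription units within 5 kb of each of the 7 MSL complex genes, by strand, against position on dm6 in kb. Bars are units drawn to scale, red for the unit of the named gene and grey for its neighbours; the red units of msl-3 and roX1 share positions with a grey unit on the other strand, by 85 bp and 392 bp.

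The lists of related genes were complete as well, with all 54 members named before the data were examined present in a unit. Of these 54 units, 16 lay on X, 4 held another gene, 17 overlapped a unit on the other strand and 30 started within 1000 bp of a divergent neighbour. In the NSL complex, the other MOF-containing complex, 1 of 6 members lay on X (wds), and 3 of 6 had a divergent neighbour within that distance. Rcd1 and Rcd5 were the closest of these, with starts 30 bp from pea and 47 bp from CG11593. Among 6 factors that recruit or work with the MSL complex, the unit of Clamp, the zinc finger protein that binds MSL recruitment sites, overlapped units on the other strand by up to 502 bp. The unit of Sxl, the female-specific repressor of msl-2, spanned 23504 bp on X and included mir-4956.

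Of 14 genes of pausing and early elongation, 10 had a divergent neighbour within 1000 bp. The starts of Cdk9, the kinase of P-TEFb, and bonsai lay 43 bp apart. Those of Nelf-A and CG3337 lay 120 bp apart, those of Nelf-E and the RpL14 unit 127 bp apart, and those of Spt5 and Fak 224 bp apart. The NELF subunit genes NELF-B and TH1, and the initiation kinase gene Cdk7, all on X, had divergent neighbours at 394 bp, 260 bp and 259 bp. CycT, the P-TEFb cyclin gene, had none nearer than 64036 bp. All 4 Pol II subunit genes of the list had a divergent neighbour within 1000 bp; the distances were 295 bp for RpII215, 243 bp for RpII140, 232 bp for RpII33 and 500 bp for RpII15. Of 11 heat shock genes, whose promoters are known for paused polymerase, 3 did. The units of Hsp70Aa and Hsp70Ab faced away from each other on 3R with starts 1991 bp apart, and the remaining Hsp70 copies of the list lay between 12465453 and 12511461 of the same arm. Reads from these near-identical copies can be hard to assign to one of them. Of 5 X-linked genes of general use, 3 overlapped a unit on the other strand: arm by 82 bp, Pgd by 104 bp and Zw by 495 bp. Act5C and SkpA overlapped none. The gene Pof, whose protein binds chromosome 4, lay on 2R and overlapped the Mmp1 unit by 284 bp.

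Units on X were longer than units on the large autosomal arms. The median was 2242 bp over 2399 X units and 1767 bp over 13340 autosomal units. The difference of medians was 0.34 on the log2 scale (95% bootstrap interval 0.28 to 0.42), or 1.27-fold. The X median also lay above that of each autosomal arm, which ranged from 1624 bp on 2L to 1888.5 bp on 3R. In a two-sided permutation test over units, p = 1e-05, the smallest that 100000 resamples can give, and 5e-05 after Benjamini-Hochberg adjustment over 5 comparisons of X with autosomes. Neighbouring units are not independent replicates. With the arm as the unit, an exact two-sided permutation test gave p = 0.20, the smallest that 5 arms allow. Units on chromosome 4 were longer still, with a median of 6955 bp. Units shorter than 1000 bp made up 24.0% of X units and 28.9% of autosomal units.

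**Figure D2:**
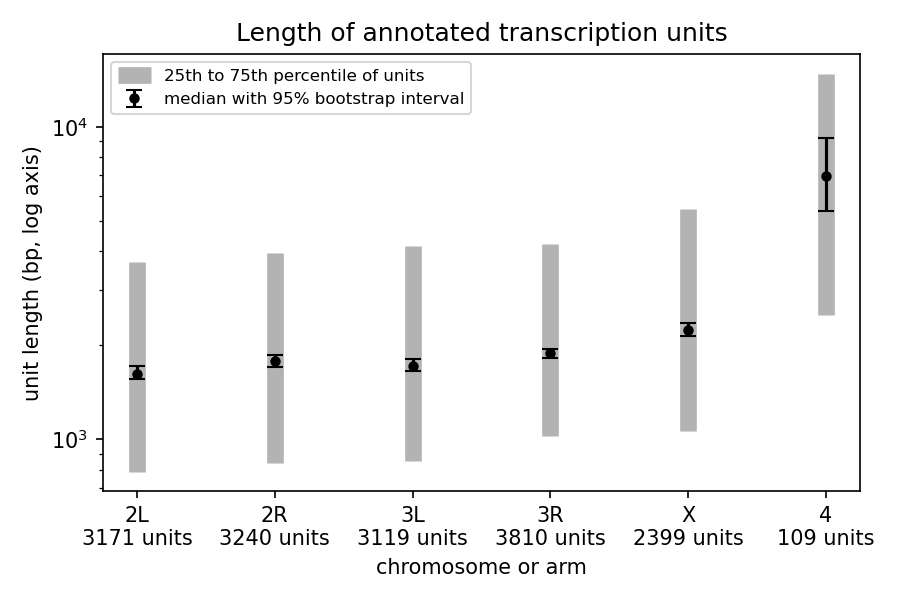
Length of transcription units in bp, on a log axis, by chromosome or arm, with the number of units under each name. Points are medians with 95% bootstrap intervals and grey bars run from the 25th to the 75th percentile; the median was 2242 bp on X, between 1624 and 1888.5 bp on the 4 large autosomal arms and 6955 bp on chromosome 4.

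The longest units each merged at least 2 genes. On X these were the kirre unit of 394149 bp with 13 genes (2740384 to 3134532), the unit of Ten-a of 291517 bp with 8 genes (12043698 to 12335214), and the unit of Atg5 and unc-119 of 239347 bp with 8 genes (7166451 to 7405797). On the autosomes they were the Myo81F unit of 1965857 bp (3R, 567076 to 2532932), the Pzl unit of 709421 bp (3R, 2554162 to 3263582) and the CG45782 unit of 434041 bp (3L, 25236940 to 25670980), each with 2 genes.

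The spacing of units on X and on the autosomes did not differ past the threshold by the 3 main measures, and passed it for each of them under another definition. The adjusted values under another definition do not cover the number of definitions tried. The median gap to the nearest unit on either strand was 72 bp on X and 69 bp on the autosomal arms. That difference, 0.06 on the log2 scale of gap plus 1 bp, had a 95% interval from -0.20 to 0.36 and a permutation p of 0.781 (adjusted 0.781). Between neighbours on the same strand the median gap was 1252 bp on X and from 837 to 1148 bp on the 4 autosomal arms, a difference of 0.32 on the log2 scale (permutation p = 5e-05, adjusted 0.000125). A unit on the other strand overlapped 38.6% of X units and 39.5% of autosomal units, a difference of -0.91 percentage points (95% interval -3.03 to 1.20; two-sided Fisher's exact p = 0.401, adjusted 0.501). Overlaps of at least 100 bp gave the opposite direction, with X higher by 2.49 percentage points (Fisher's exact p = 0.0141, adjusted 0.0235). Divergent start sites at most 1000 bp apart were found for 32.5% of X units and 33.5% of autosomal units, a difference of -0.99 percentage points (95% interval -3.03 to 1.05; Fisher's exact p = 0.347, adjusted 0.501). At most 500 bp apart, the difference was -2.30 percentage points (Fisher's exact p = 0.0165, adjusted 0.0276). Both units of an overlap or divergent pair were counted in these Fisher's tests, so the counts are not independent and the p-values may be too small. A gap between units that are each other's nearest neighbour likewise entered the permutation tests for both units. Those p-values, that of the same-strand gap included, may also be too small. No test with the arm as the unit was made for the other definitions. By the main definitions, neither the gap on either strand, the overlap nor the divergent share on X lay outside the range of the 4 autosomal arms.

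Nearly all annotated protein-coding genes had a unit. Spans are nearly all identical between the annotation and the gene table, so this match is not an independent check of the units. On X, 2172 of 2197 protein-coding genes of the RefSeq table were matched by name to a unit (98.9%), against 11592 of 11645 on the autosomal arms (99.5%). The difference of -0.68 percentage points (95% interval -1.14 to -0.22) passed Fisher's exact test (two-sided p = 0.000451, adjusted 0.00113), and X was lower than each autosomal arm, the lowest of which stood at 99.4%. With the arm as the unit, an exact two-sided permutation test gave p = 0.20, the smallest that 5 arms allow. Of the 25 X genes without a match, 19 formed a single run from CG46504 to CG46522, between 22147789 and 22247475. Without that run, a removal chosen because its genes were unmatched, the difference was 0.18 percentage points in the other direction. Fisher's test counts neighbouring genes as independent. With whole blocks of genes moved between X and autosomes in a two-sided permutation test added after the run was seen, p was 0.0250 for blocks of 100 kb and 0.123 for blocks of 1000 kb.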

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

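No paired analysis was possible because no values of the libraries were analysed, and replicates could not be left out for the same reason. The longer X units kept their direction and their side of the threshold under all 10 alternatives tried, with differences from 0.31 to 0.39 on the log2 scale; the longest unit of each gene was no real alternative, since every gene lies in 1 unit. The gap to the nearest unit passed the threshold only for neighbours on the same strand, where X gaps were larger by 0.32. The X share of units rose to 16.1% among units of at least 1000 bp. With overlaps of at least 100 bp the X minus autosome difference in overlap turned to 2.49 percentage points, and over the 5 arms the overlapping share was 28.6% in place of 39.4%, and 0% on the same strand alone. With start sites at most 500 bp apart the difference in divergent share was -2.30 percentage points and passed the threshold, in a test that counts both units of a pair. The divergent share over the 5 arms was 24.5% at 500 bp and 41.2% at 2000 bp in place of 33.3% at 1000 bp. The lower share of X genes with a unit kept its call with all gene classes (-0.57 percentage points) and with exact spans also counted as matches (-0.70). It lost its call with current symbols alone (-0.27 percentage points). The difference reversed to 0.18 percentage points without the run of 19 genes and to 0.083 with each run of unmatched genes counted once. The last 2 were chosen by which genes were unmatched, so they do not test the difference. Matching by current symbols alone or also by exact span and the 2 treatments of runs were chosen after seeing the data. So were units that hold 1 gene and units that hold only protein-coding genes. For the same-strand gap, the larger overlap, the other divergent distances and the longer units, the cause of the change was not tested. Matching by current symbols alone leaves out the 3534 genes of all classes matched by locus tag or synonym, though each is named in a unit. That alternative therefore counts differing names as missing units.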

Other observations

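The explanatory tests in this part, those of merging, gene classes, gene names, blocks of genes and divergent pairs, were all chosen after the data were first examined. Protein-coding genes were most of the 2851 genes in units with several genes (1918), but the share of a class that was merged was highest for small RNA genes, which gave 498 (snoRNA, miRNA, tRNA and snRNA genes). Of 258 snoRNA genes matched to the RefSeq table, 94.6% (95% exact interval 91.1 to 97.0%) lay in a unit with another gene, and 77.1% shared it with a protein-coding gene. For 256 miRNA genes these shares were 71.9% (65.9 to 77.3%) and 54.3%, and for 290 tRNA genes both were 20.3% (15.9 to 25.4%). Of 13866 protein-coding genes, 13.8% (13.3 to 14.4%) shared a unit. The 2 units with the most genes, 18 each, were those of Arpc2, an Arp2/3 complex subunit gene, on 2L from 20417057 to 20423027 and of dom, a chromatin remodeller gene, on 2R from 21323430 to 21341847; nearly all of their other genes were snoRNAs. Next, with 17 genes each, came the units of Uhg1 and SLO2 on 2R. The other genes of the Uhg1 unit were snoRNAs, and the SLO2 unit named none. On X the ribosomal protein gene RpS5a had 15 genes in its unit, from 17143588 to 17148264. The mod(mdg4) unit on 3R also held 15. These units were singled out after their values were seen.

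A gene merged into a longer unit can start away from the start of the unit. The start of 662 of 13866 protein-coding genes (4.77%) lay over 100 bp from the start of their unit. On X the share was 6.22% (135 of 2172 genes; 95% exact interval 5.24 to 7.31%), and on the autosomal arms it ran from 3.61% on 3R to 5.36% on 3L. The difference was not tested.

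X units were longer than autosomal ones, also where no genes were merged. Among units that hold 1 gene the difference in median log2 length was 0.33 (95% interval 0.23 to 0.41), above the bound of 0.17 below which merging would have explained most of it. Multi-gene units were 7.34% of units on X and 7.06% to 7.34% on the autosomal arms. Leaving out so few could move the medians only a little, so the bound was unlikely to be reached. Staying above it therefore says little about merging. The mix of gene classes does not account for the longer X units. Among units that hold only protein-coding genes the difference was 0.31 (0.22 to 0.39), with medians of 2575 bp on X and 2074 bp on the autosomes. Since 14682 single-gene units have exactly the span of their gene in the RefSeq table and 115 do not, the difference lies in the annotated spans of the X genes themselves (medians of 2069 bp on X and 1649 bp on the autosomes over single-gene units). Why these spans are longer, and whether annotated ends are equally complete on X and autosomes, was not tested.

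Names that differ between the annotation and the RefSeq table could lower the share of X protein-coding genes with a unit. Of the 25 unmatched X genes, 12% (3 genes, 95% exact interval 2.55 to 31.2%) had exactly the start and end of a unit. On the autosomal arms 18 of 53 did. Counting such genes as matched left the X minus autosome difference at -0.70 percentage points. Of the 25, 19 are the run CG46504 to CG46522, genes of 875 or 876 bp that start 4732 to 10145 bp apart over 99.7 kb, and none of the units analysed here lies in that stretch. No exact span was possible there, so these 19 are not independent trials and the interval for the 25 genes is largely set by the run. The 12% therefore does not decide how far names matter, though those 19 have no unit there under another name. Neighbouring genes counted as independent could have made Fisher's p too small. With whole blocks of genes, matched or not, moved between X and autosomes, the two-sided permutation p was 0.0250 for blocks of 100 kb (225 on X, 992 on the autosomes) and 0.123 for blocks of 1000 kb (24 and 110), with the 19-gene run split over 2 blocks at the smaller size. The bound of 0.05 on the 100-kb blocks does not count as preset, since its wording was changed and restored after both values were seen. The difference passed it with the 100-kb blocks and did not with the 1000-kb blocks. The call therefore depends on the block size, and the dependence of neighbours is not excluded as its source. Whether the stretch is empty because the genes entered the gene table after the annotation was built, or because of the copy of the annotation analysed here, stays open, and neither was tested.

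A hypothesis is that the genes of the fixed lists start in divergent pairs more often than protein-coding genes at large. Over all lists together, 30 of 54 units (55.6%; 95% exact interval 41.4 to 69.1%) had a divergent start within 1000 bp, against 36.5% of 12367 other units that hold only protein-coding genes (two-sided Fisher's exact p = 0.00454). The 54 include 4 units that do not hold only protein-coding genes, those of roX1, roX2, msl-2 with mir-4971 and Sxl with mir-4956. Over the other 50, 29 had such a start (58%; 43.2 to 71.8%; Fisher's exact p = 0.00283). None of the 7 lists with several members passed on its own after Benjamini-Hochberg adjustment over them. The lowest adjusted values were 0.0623 for pausing and early elongation (10 of 14) and 0.0623 for the Pol II subunits (4 of 4). These 2 lists also had the highest shares, so the pooled result does not speak for each list. The MSL complex had 3 of 7, the NSL complex 3 of 6, MSL recruitment and partners 3 of 6 and the X-linked genes 3 of 5. The heat shock list was below the other units (3 of 11, 27.3%). The counts were seen before the test was chosen, and genes used in every cell may pair this way whatever their function, which the annotation alone cannot show.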
